A study of Homo sapiens with 18 samples.

How the data were processed

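The study profiled total RNA from LNCaP and LNCaP-abl prostate cancer cells on 18 one-colour Affymetrix arrays in 6 groups of 3: LNCaP with control or TRIM24 siRNA, each with vehicle or 10 nM DHT, and LNCaP-abl with control or TRIM24 siRNA and vehicle. Cells were transfected for 48 h and treated for 24 h, per the labels' protocols. The values are log2 expression values as the authors deposited them, made with RMA per the submitters' processing notes; RMA summarises several probes into 1 value per probe set. The version of RMA and the scan dates are not given in the sources used here. The table holds 54675 probe sets, of which 62 are controls. The values were used as deposited, with no further scaling in the main result. RMA draws arrays to a common distribution of probe signals, so a change shared by most transcripts would not be seen, and values near the lower end are compressed, which makes the changes of dim genes smaller than they were.

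Probe sets were named from a table of the platform's annotation, which can be old. A single gene symbol was listed for 41097 probe sets, several for 1801 and none for 11777; probe sets with several symbols named no gene. Symbols were updated through the gene identifier of a human RefSeq gene table for 41043 probe sets. Each of the 19775 genes was represented by the probe set with the highest mean over the 18 arrays. A gene was tested if its third-highest value reached 5.88, the median of the table, which kept 13607 genes.

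A group-means model of all 18 arrays was fitted with limma (version 3.58.1, R version 4.3.3), with 12 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment over the 13607 genes of each comparison. A gene was called at an adjusted p under 0.05. The 8 comparisons were knockdown in LNCaP with vehicle, knockdown in LNCaP with DHT, knockdown in LNCaP-abl, DHT with each siRNA, LNCaP-abl against LNCaP with control siRNA, and the interactions of knockdown with DHT and with cell line. The median residual SD was 0.073. Fold changes are differences of mean log2 values with their standard errors, and all tests were two-sided. The precision is limited by the number of arrays, 3 per group.

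Before the data were examined, 17 gene lists with 330 genes were fixed, of which 268 genes were measured: androgen-induced, androgen-repressed, G1/S and DNA replication, G2/M and mitosis, interferon-stimulated, retinoic acid-induced, p53 target, cholesterol and fatty acid synthesis, glycolysis, ER stress and amino acid response, and MYC-linked ribosome biogenesis genes, and neuroendocrine, luminal, basal, fibroblast and mesenchymal, and leukocyte and endothelial markers. The remaining list and some list members are not reported here. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with the rotation test fry, which tests a list against no change and not against other genes, each adjusted over the 17 lists of a comparison. Of 136 list tests 49 passed with the preset correlation and 33 of these held with an estimated one. The 4 of knockdown in LNCaP with vehicle, 6 of knockdown in LNCaP-abl and 3 of LNCaP-abl against LNCaP all held; 2 of 7 held for knockdown with DHT, 4 of 9 and 6 of 8 for DHT with control and TRIM24 siRNA, and 3 of 5 and 5 of 7 for the interactions with DHT and cell line.

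Named genes followed a rule fixed at the same time. It took TRIM24, then the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap, then up to 4 members per list with the smallest adjusted p, and for the interactions the 5 largest in each direction. The text names a selection of these. List members named for the interactions and members outside the rule, such as genes that moved against the rest of their list, were chosen after their values were seen.

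The alternatives were a missing and a stricter low-value filter, other ways to choose or average the probe sets of a gene, every probe set tested alone, median centring and quantile normalization, only the groups compared in the fit, an intensity trend with robust variances, array weights, other thresholds, the replicate number as a block, and the omission of each array in turn. A covariate for the 3' to 5' signal of the GAPDH and ACTB control probe sets, the omission of cell cycle genes from the DHT sets, and a list comparison of knocked-down LNCaP-abl with control LNCaP were added after the data were seen. The linear-scale alternative did not apply because the values are on a log2 scale.

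The fit was tested on simulated data drawn from the real group means and residual SDs of 13607 genes, with the knockdown group first set equal to its control. In each of the 3 knockdown comparisons, 100 genes per size were changed. At a log2 change of 0.25 the fit recovered 46, 51 and 54 of the 100 in LNCaP with vehicle, LNCaP with DHT and LNCaP-abl, and at 0.5 it recovered 95, 97 and 97. Of 151, 153 and 160 calls 10, 5 and 9 were false. For camera, a list lowered in LNCaP with vehicle was recovered in each of 20 simulated data sets, and 3 of 320 tests of unshifted lists passed. Genes were drawn independently, so these draws do not test camera on lists whose genes are correlated. In the test of single genes 200 genes were changed, far fewer than were called in the data, so the recovered shares may not carry over.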

Results

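Gene expression was measured on 18 Affymetrix arrays of total RNA from LNCaP, an androgen-responsive human prostate cancer cell line, and LNCaP-abl, a derivative of LNCaP that grows without androgen. Cells were transfected for 48 h with a control siRNA or with siRNA against TRIM24, a bromodomain-containing chromatin reader and ubiquitin ligase that acts as a cofactor of nuclear receptors. LNCaP cells received vehicle or 10 nM dihydrotestosterone (DHT), the active androgen, for 24 h, and LNCaP-abl cells received vehicle. This gave 6 groups of 3 arrays. Array medians lay between 5.83 and 5.93 on the log2 scale, and arrays of 1 group correlated at 0.996 to 0.998 across probe sets, which are not independent. The number of arrays limits the precision of every value. Of 234 values of named genes 42 involve a group with a mean below 5.88, the value used as a filter, where changes are compressed. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The comparisons ask which genes depend on TRIM24 in the androgen-responsive line with and without hormone, and in the line that has outgrown the need for it.

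TRIM24 itself was lower on each array with its siRNA than on each control array. In LNCaP with vehicle the control arrays read 9.69, 9.71 and 9.71 and the knockdown arrays 7.73, 7.70 and 7.69 (log2). With DHT the control arrays read 10.12, 10.13 and 10.17 and the knockdown arrays 8.09, 8.04 and 7.89. In LNCaP-abl the control arrays read 9.44, 9.60 and 9.55 and the knockdown arrays 7.45, 7.55 and 7.35. The log2 fold change was -1.99 ± 0.05 in LNCaP with vehicle, -2.14 ± 0.05 with DHT and -2.08 ± 0.05 in LNCaP-abl (SE, n = 3 arrays per group), which left 25.1%, 22.7% and 23.6% of the control signal. These values come from the brightest of 4 TRIM24 probe sets, of a kind that can also bind related transcripts. A further bright probe set gave -2.00, -2.17 and -1.98. Of the dim ones, 1 gave -0.79, -1.69 and -0.90 and the other gave 0.02, -0.13 and 0.08, so it did not follow the knockdown. The mean of the 4 was -1.19 with vehicle and -1.22 in LNCaP-abl. RNA quality moved with the siRNA as well. The log2 signal at the 3' end over the 5' end of the GAPDH control probe sets was 0.52 ± 0.03 in control and 0.59 ± 0.02 in knockdown cells with vehicle, 0.55 ± 0.02 and 0.63 ± 0.01 with DHT, and 0.56 ± 0.02 and 0.64 ± 0.02 in LNCaP-abl (SD, n = 3). For ACTB it was 1.87 ± 0.05 and 2.05 ± 0.08 with vehicle, 1.85 ± 0.09 and 2.18 ± 0.07 with DHT, and 1.88 ± 0.09 and 1.99 ± 0.09 in LNCaP-abl.

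**Figure D1:**
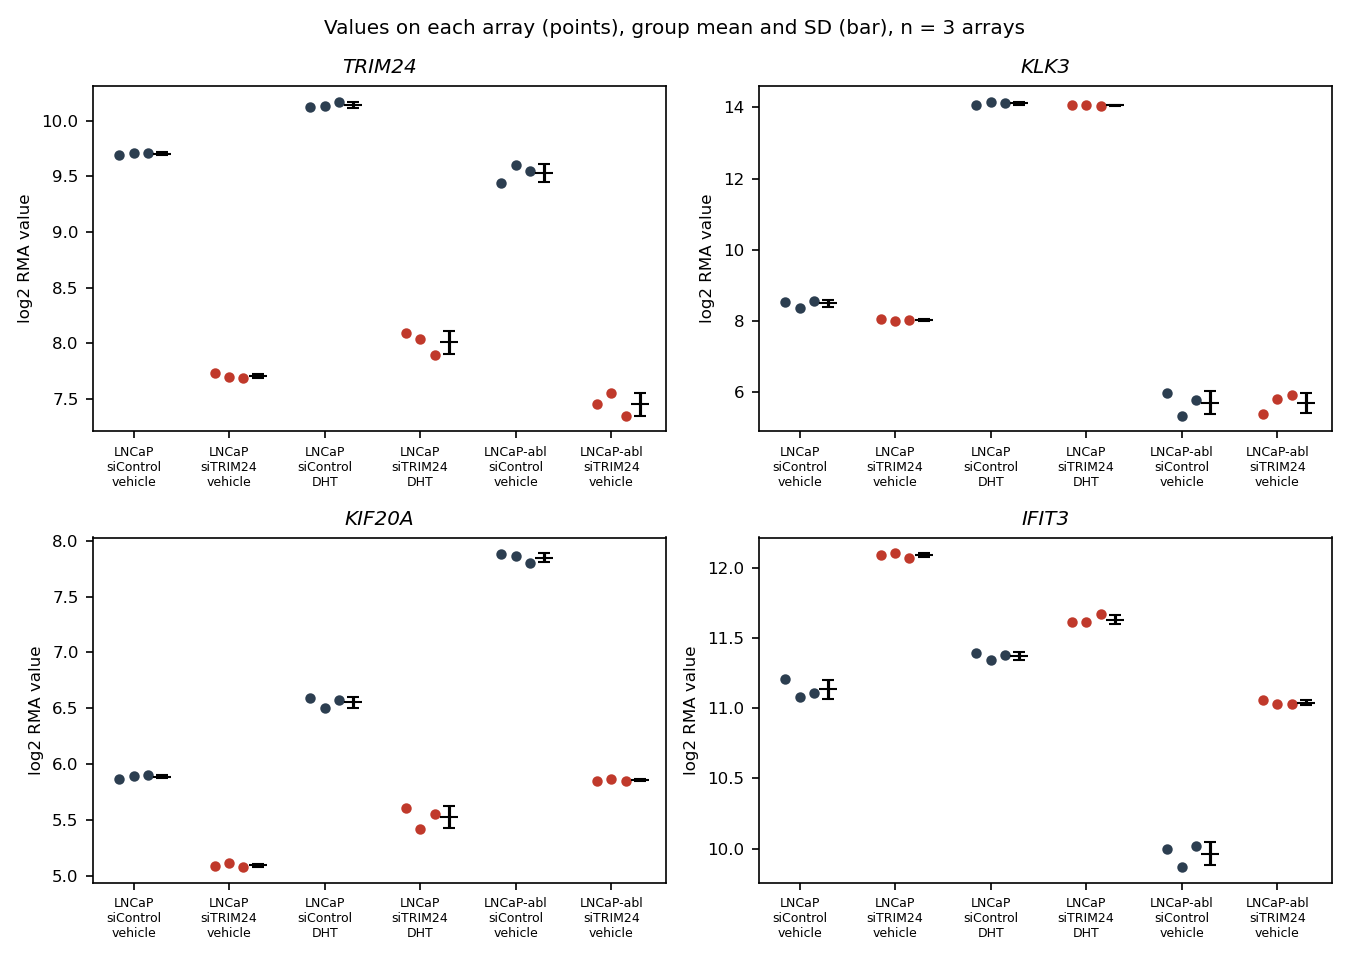
Log2 RMA values of TRIM24, KLK3, KIF20A and IFIT3 on each of the 18 arrays by group, with the group mean and SD beside the points (n = 3 arrays; red, TRIM24 siRNA). TRIM24 changed by -1.99, -2.14 and -2.08 with its siRNA, and KLK3 stood at 8.50 with vehicle and 14.12 with DHT in control LNCaP.

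In LNCaP cells without hormone, knockdown of TRIM24 lowered genes of mitosis and raised genes of the interferon response. Of 30 measured G2/M and mitosis genes 24 fell and none rose (26 fell when adjusted over the list alone), with a median log2 fold change of -0.43. KIF20A, a kinesin of cytokinesis, fell by 0.79 ± 0.04, CENPF, a kinetochore protein, by 1.15 ± 0.08, and BIRC5, the mitotic regulator survivin, by 0.73 ± 0.05 (SE, n = 3 per group). After knockdown KIF20A and CENPF had means of 5.1 and 5.69, below 5.88, so their falls can be too small. Averaging a gene's probe sets put CENPF at -0.57 and BIRC5 at -0.46. Of 28 interferon-stimulated genes 18 rose and none fell (18 when adjusted over the list alone), with a median of 0.27. The antiviral genes OASL, IFIT2 and IFIT3 rose by 1.01 ± 0.04, 1.05 ± 0.05 and 0.95 ± 0.04. The IFIT genes are paralogs whose probe sets can share signal. Camera, a test of a list against all other genes, gave an adjusted p of 2.7e-11 for the mitosis list and 1.34e-08 for the interferon list. In these same arrays the GAPDH 3' to 5' log2 signal moved from 0.52 to 0.59.

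The androgen-induced genes moved in both directions in this comparison. Of 24 measured members 11 fell and 3 rose (11 and 4 when adjusted over the list alone), the median was -0.13 and camera gave an adjusted p of 0.0104. SLC45A3, the prostate antigen prostein, fell by 1.69 ± 0.06, ELL2, a transcription elongation factor, by 0.94 ± 0.08 and FKBP5, a chaperone partner of steroid receptors, by 0.47 ± 0.04. PTGER4, a prostaglandin receptor, rose by 0.99 ± 0.13, as did ZBTB10 and NDRG1 by 0.27 ± 0.06 and 0.18 ± 0.06; these 3 were named after their values were seen. Without the third control array NDRG1 was at 0.10 (adjusted p = 0.104), and with the 3' to 5' covariate ZBTB10 was at 0.20 (adjusted p = 0.103). With the most variable probe set of each gene the list's adjusted p was 0.0971 and its median -0.065. Of 19 p53 target genes 9 fell and 2 rose (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0104), among them TP53INP1, a stress-induced autophagy and cell death gene, with a fall of 0.68 ± 0.04. The death receptor gene TNFRSF10B rose by 0.51 ± 0.03, and with its most variable probe set it was at 0.12 (adjusted p = 0.0644). Of 29 G1/S and DNA replication genes 7 rose and 5 fell (camera adjusted p = 0.93), with FEN1, a flap endonuclease, at 0.48 ± 0.05 and TYMS, the thymidylate synthase, at -0.69 ± 0.04. Their median was 0.04 and their mean -0.01. Of 10 androgen-repressed genes 5 fell and 2 rose (camera adjusted p = 0.534), with OPRK1, the kappa opioid receptor, at -1.01 ± 0.07 and CAMK2N1, an inhibitor of CaM kinase II, at 0.50 ± 0.05.

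The largest rises were in DPY19L1, a mannosyltransferase, at 1.81 ± 0.09, MPZL3 at 1.65 ± 0.04, GOLT1B, a vesicle transport protein, at 1.64 ± 0.05 and the laminin subunit LAMC1 at 1.62 ± 0.03. The chemokines CXCL8 and CCL20 rose by 1.51 ± 0.11 and 1.45 ± 0.10. The largest falls besides TRIM24 were in SPCS3, a subunit of the signal peptidase, at -2.05 ± 0.04, MZT1, a component of microtubule nucleation complexes, at -1.92 ± 0.06, NAALADL2 at -1.88 ± 0.10 and PHACTR2 at -1.85 ± 0.08. CCL20 in control cells and NAALADL2 after knockdown had means of 5.08 and 5.14, below 5.88, so their changes can be too small. A further probe set of LAMC1 changed the other way, at -0.20, and averaging the probe sets of a gene put LAMC1 at 0.71, MPZL3 at 0.64, GOLT1B at 0.92, SPCS3 at -0.85 and MZT1 at -1.21. In limma with Benjamini-Hochberg adjustment, 5236 of 13607 genes passed an adjusted p of 0.05, 2792 higher and 2444 lower. The median size of a called change was 0.26, and 106 genes changed at least 2-fold, 33 up and 73 down. The arrays of both groups did not overlap for 50.9% of genes, where chance gives 10%.

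With DHT present, knockdown again lowered mitotic genes, and the interferon genes rose less. Of 30 G2/M and mitosis genes 25 fell and none rose (25 when adjusted over the list alone), the median was -0.59 and camera gave an adjusted p of 9e-15. DLGAP5, a spindle protein, fell by 1.37 ± 0.07, KIF20A by 1.03 ± 0.04 and CCNB2, a mitotic cyclin, by 0.89 ± 0.04 (SE, n = 3 per group). As the mean of its probe sets CCNB2 was at -0.30. Of 28 interferon-stimulated genes 12 rose and 3 fell (12 and 3 when adjusted over the list alone), with OASL at 0.35 ± 0.04 and IFIT3 at 0.26 ± 0.04. The interferon list had a camera adjusted p of 0.0435, which became an adjusted p of 0.199 with an estimated correlation. The 3 that fell, named after their values were seen, were the RNA sensor RIGI at -0.24 ± 0.05, USP18, a protease that damps interferon signalling, at -0.21 ± 0.05 and IFIT5 at -0.19 ± 0.07. IFIT5 lost its call without any of 4 arrays, with adjusted p-values up to 0.142 without the third control DHT array, and RIGI was at -0.02 (adjusted p = 0.699) as the mean of its probe sets. With the 3' to 5' covariate IFIT3 was at 0.23 (adjusted p = 0.0711). The GAPDH 3' to 5' log2 signal moved from 0.55 to 0.63 in these arrays.

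Of 24 androgen-induced genes 11 fell and 3 rose with knockdown under DHT (11 and 3 when adjusted over the list alone; median -0.11, camera adjusted p = 0.0346). The list gave an adjusted p of 0.0853 with an estimated correlation, and its median was -0.054 without the third knockdown array. ELL2 fell by 1.06 ± 0.08, SLC45A3 by 0.99 ± 0.06 and C1orf116 by 0.57 ± 0.05. KLK2, a kallikrein protease closely related to KLK3, fell by 0.54 ± 0.07, while KLK3, which encodes prostate-specific antigen, was at -0.05 ± 0.13 and did not pass. The SE of KLK3 pools all 18 arrays, and those of LNCaP-abl, where KLK3 was dim, scattered from 5.35 to 5.99. Under DHT its arrays read 14.05 to 14.16, near the array maxima of 14.73 to 14.83, where a change can be compressed. A further bright KLK3 probe set read 14.36 to 14.40 in control and 14.32 to 14.34 in knockdown arrays with DHT. With vehicle, where it was dimmer, KLK3 fell by 0.47 ± 0.13 with knockdown, a value looked up after the result with DHT was seen. Of 10 androgen-repressed genes 4 rose and 1 fell (camera adjusted p = 0.0435; adjusted p = 0.116 with an estimated correlation; 0.0532 after quantile normalization). CAMK2N1 rose by 1.16 ± 0.05 and UGT2B15 and UGT2B28, androgen-glucuronidating enzymes encoded by related genes, by 0.60 ± 0.04 and 0.60 ± 0.05, while OPRK1 fell by 0.58 ± 0.07. Of 29 G1/S and DNA replication genes 12 fell and 4 rose (13 and 4 when adjusted over the list alone; median -0.14, camera adjusted p = 0.0369; adjusted p = 0.246 with an estimated correlation). The adjusted p was 0.0612 without the first control DHT array and 0.053 without the second knockdown DHT array. TYMS fell by 0.88 ± 0.04 and the cyclin gene CCNE2 by 0.67 ± 0.09. Of 19 p53 target genes 10 fell and 1 rose (10 and 1 when adjusted over the list alone; camera adjusted p = 0.0158), with TP53INP1 at -1.16 ± 0.04 and TNFRSF10B at 0.46 ± 0.03. Of 18 glycolysis genes 10 rose and 1 fell (11 and 2 when adjusted over the list alone; camera adjusted p = 0.0369; adjusted p = 0.204 with an estimated correlation), with HK2, a hexokinase, at 0.72 ± 0.05 and LDHA, the lactate dehydrogenase, at 0.36 ± 0.03. After centring each array on its median 6 glycolysis genes rose and 2 fell, and after quantile normalization 10 rose and none fell.

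The amino acid transporter SLC7A2 rose most, by 1.93 ± 0.04, followed by MPZL3 at 1.83 ± 0.04 and GOLT1B at 1.65 ± 0.05. CDK6, a kinase of the G1 phase, rose by 1.42 ± 0.08. The falls were led, after TRIM24, by PHACTR2 at -2.07 ± 0.08, MZT1 at -1.91 ± 0.06, the cytokine gene TNFSF4 at -1.56 ± 0.06 and TIMP2, an inhibitor of matrix metalloproteinases, at -1.55 ± 0.05. These sizes and their order depended on the choice of probe set. Averaging a gene's probe sets put SLC7A2 at 0.70, MPZL3 at 0.76, GOLT1B at 1.08, CDK6 at 0.71, MZT1 at -1.01 and TIMP2 at -0.91. In limma 5468 of 13607 genes passed, 2644 higher and 2824 lower, and 106 changed at least 2-fold, 24 up and 82 down. After centring each array on its median 2290 were higher and 2881 lower, and after quantile normalization 2811 and 2672. The groups did not overlap for 49.7% of genes against 10% by chance. With the 3' to 5' signal as a covariate, an alternative added after seeing the data, 2669 genes passed.

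In LNCaP-abl, knockdown lowered genes of DNA replication together with genes of mitosis, and by more than in LNCaP. Of 30 G2/M and mitosis genes 28 fell and none rose (28 when adjusted over the list alone), with a median of -1.70. KIF20A was at -1.99 ± 0.04, CCNB2 at -1.72 ± 0.04 and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, at -1.70 ± 0.04 (SE, n = 3 per group). As the mean of its probe sets CCNB2 was at -0.59. KIF20A had means below 5.88 after knockdown in LNCaP with vehicle, LNCaP with DHT and LNCaP-abl, at 5.1, 5.53 and 5.85. Its falls can therefore be too small and are uncertain to compare. Of 29 G1/S and DNA replication genes 28 fell and none rose (28 when adjusted over the list alone), with a median of -0.88. UHRF1, which maintains DNA methylation at replication forks, fell by 1.83 ± 0.08, RRM2, a subunit of ribonucleotide reductase, by 1.77 ± 0.06 and MCM5, part of the replicative helicase, by 1.30 ± 0.06. Camera gave adjusted p-values of 3.31e-25 for the mitosis list and 1.55e-17 for the replication list. The GAPDH 3' to 5' log2 signal moved from 0.56 to 0.64 in these arrays.

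Interferon genes rose with knockdown in LNCaP-abl as well. Of 28 members 17 rose and 2 fell (17 and 2 when adjusted over the list alone; median 0.38, camera adjusted p = 9.49e-09), with RSAD2, the antiviral enzyme viperin, at 1.23 ± 0.06, IFIT3 at 1.08 ± 0.04 and OASL at 1.06 ± 0.04. The 2 that fell, named after their values were seen, were IFIT5 at -0.32 ± 0.07 and USP18 at -0.14 ± 0.05. USP18 lost its call without any of 4 arrays, down to -0.08 (adjusted p = 0.185) without the first knockdown array, and was at -0.04 (adjusted p = 0.548) after quantile normalization. Of 18 glycolysis genes 14 fell and none rose (15 when adjusted over the list alone; camera adjusted p = 0.000813), with PFKP, a phosphofructokinase, at -0.51 ± 0.04 and LDHA at -0.36 ± 0.03. Of 18 MYC-linked ribosome biogenesis genes 14 fell and 1 rose (15 and 1 when adjusted over the list alone; camera adjusted p = 0.00232). ODC1, the ornithine decarboxylase of polyamine synthesis, fell by 0.55 ± 0.03 and the rRNA processing gene RRP12 by 0.47 ± 0.05, while MYC itself was the member that rose, by 0.23 ± 0.04. Of 24 androgen-induced genes 13 fell and 2 rose (13 and 2 when adjusted over the list alone), and the list's camera adjusted p of 0.0598 did not pass. SLC45A3 fell by 1.19 ± 0.06 and FKBP5 by 0.91 ± 0.04, while MAF and TMPRSS2 rose by 0.46 ± 0.10 and 0.32 ± 0.04. CENPN, a centromere protein on this list, fell by 1.28 ± 0.04. The list's adjusted p was 0.0378, 0.0485 and 0.0358 without the second control, the third control or the second knockdown array of LNCaP-abl. Of 10 androgen-repressed genes 7 rose and 1 fell (7 and 1 when adjusted over the list alone; camera adjusted p = 0.00607), with CAMK2N1 at 0.68 ± 0.05, FOLH1, the prostate-specific membrane antigen, at 0.44 ± 0.08 and OPRK1 at -0.53 ± 0.07. Of 19 p53 target genes 9 fell and 5 rose (camera adjusted p = 0.879), with TP53INP1 at -0.33 ± 0.04 and GDF15, a stress-induced cytokine, at 0.32 ± 0.05. After quantile normalization 4 p53 target genes fell and 5 rose, and after centring 10 fell and 5 rose. As means of their probe sets TP53INP1 was at -0.07 (adjusted p = 0.404), GDF15 at 0.10 (adjusted p = 0.253), RRP12 at -0.07 (adjusted p = 0.242) and MAF at 0.15 (adjusted p = 0.0982).

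The largest falls were in MCM10, a replication initiation factor, at -2.52 ± 0.17, ZNF367 at -2.31 ± 0.13, SPC25 and KNL1, both kinetochore proteins, at -2.28 ± 0.14 and -2.26 ± 0.10, and SHCBP1 at -2.22 ± 0.10, with CCNA2, the cyclin of S phase and mitotic entry, close by at -2.11 ± 0.11. MCM10, ZNF367 and SPC25 had means below 5.88 after knockdown, so their falls can be too small. The largest rises included LAMC1 at 1.67 ± 0.03, MPZL3 at 1.39 ± 0.04, GOLT1B at 1.35 ± 0.05 and the chemokines CCL20 and CCL5 at 1.32 ± 0.10 and 1.29 ± 0.08. Averaging a gene's probe sets put LAMC1 at 0.895, MPZL3 at 0.50 and GOLT1B at 0.79. In limma 6201 of 13607 genes passed, 2276 higher and 3925 lower, and 171 changed at least 2-fold, 12 up and 159 down. The split between higher and lower genes depended on scaling, with 1608 higher and 4528 lower after centring each array on its median and 3022 and 3126 after quantile normalization. The groups did not overlap for 52% of genes against 10% by chance.

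**Figure D2:**
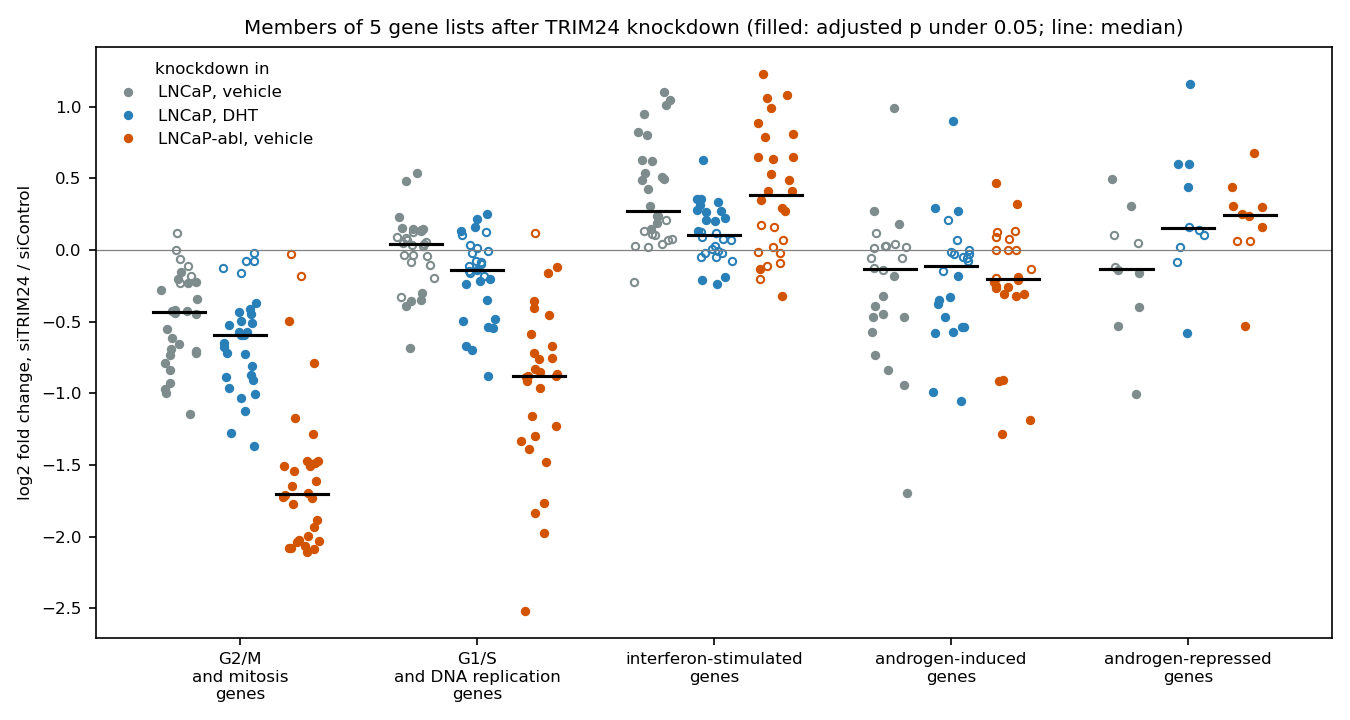
Log2 fold change with TRIM24 siRNA over control siRNA (vertical axis) for the measured members of 5 gene lists in each knockdown comparison; filled points passed an adjusted p of 0.05 and black lines are medians. The G2/M and mitosis medians are -0.43, -0.59 and -1.70, and the G1/S medians are 0.04, -0.14 and -0.88.

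A common set of genes changed with TRIM24 siRNA in the 3 knockdown comparisons, which share no arrays. Nothing here separates loss of TRIM24 from effects of the siRNA sequence on other transcripts, which can recur across comparisons too. Among 13607 genes 919 were called higher and 1535 lower in all 3, where independent lists of these sizes would share 90.7 and 146.3. Of these 7 rose and 24 fell at least 2-fold in each comparison. The largest mean rises were in MPZL3 at 1.62, LAMC1 at 1.57, SLC7A2 at 1.56 and DPY19L1 and GOLT1B at 1.55, and CCL20 and CLDN12, a claudin of tight junctions, followed at 1.33 and 1.26. These values use 1 probe set per gene. Averaging a gene's probe sets put MPZL3 at 0.64, 0.76 and 0.50 in LNCaP with vehicle, LNCaP with DHT and LNCaP-abl. For GOLT1B it gave 0.92, 1.08 and 0.79. SLC7A2 stood at 0.70 with DHT by this average. The largest mean falls after TRIM24 were in MZT1 at -1.97, PHACTR2 at -1.78, SPCS3 at -1.59, ZBTB37 at -1.55, the annexin partner S100A10 at -1.50 and CENPF at -1.48. With DHT 2 further probe sets of SPCS3 did not follow, at -0.07 (not called) and 0.18 (called the other way). Within LNCaP, 1666 genes were higher and 1764 lower with knockdown in both hormone conditions, against 542.5 and 507.2 for independent lists. Between LNCaP and LNCaP-abl, both with vehicle, 1137 genes were higher and 1803 lower, against 467 and 705. Fold changes correlated across genes at 0.77 between the LNCaP comparisons, 0.57 between the lines with vehicle and 0.65 between LNCaP with DHT and LNCaP-abl; genes are not independent. With the 3' to 5' covariate the calls shared by both LNCaP comparisons went from 3430 to 1964.

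The effect of knockdown differed between the lines for the cell cycle genes. The interaction, the LNCaP-abl change minus the LNCaP change with vehicle, was negative for 28 of 30 G2/M and mitosis genes and 28 of 29 G1/S genes at an adjusted p of 0.05 (28 and 28 when adjusted over the list alone). The medians were -1.13 and -0.87, and the camera adjusted p-values 5.35e-26 and 9.01e-24. MCM10 had an interaction of -2.19 ± 0.24 (-0.33 in LNCaP and -2.52 in LNCaP-abl), and DTL, a substrate receptor of a replication-coupled ubiquitin ligase, of -2.01 ± 0.16 (0.03 and -1.98). ZNF367, SHCBP1 and DEPDC1B had interactions of -2.13 ± 0.19, -2.09 ± 0.14 and -2.03 ± 0.13. Of 18 MYC-linked genes 12 had a negative interaction and none a positive one (13 when adjusted over the list alone; camera adjusted p = 0.000711). For androgen-repressed genes 7 of 10 interactions were positive (camera adjusted p = 2.48e-05), with FOLH1 at 0.84 ± 0.11 and UGT2B17 at 0.60 ± 0.10. The p53 target list had 5 positive and 1 negative interaction of 19 (camera adjusted p = 0.0103). Of 18 glycolysis genes 8 were negative (camera adjusted p = 0.03; adjusted p = 0.197 with an estimated correlation), and of 20 ER stress genes 7 were positive and 2 negative (camera adjusted p = 0.0118; adjusted p = 0.096 with an estimated correlation). The interferon list showed 5 positive and 6 negative interactions of 28 (camera adjusted p = 0.494). Positive interactions were largest for NAALADL2, a peptidase-like protein, at 1.52 ± 0.14, the long noncoding RNA PSLNR at 1.33 ± 0.12 and the transcription factor MAF at 1.30 ± 0.15. MCM10, DTL, ZNF367, SHCBP1 and DEPDC1B in LNCaP and NAALADL2 and MAF in LNCaP-abl had means below 5.88, where a change cannot be measured well. MCM10, ZNF367 and DEPDC1B were also below it in knocked-down LNCaP-abl, and NAALADL2 in knocked-down LNCaP. These interactions can therefore be too large or too small. TRIM24 had an interaction of -0.09 ± 0.08 (adjusted p = 0.425). In limma 3884 genes passed, 109 of them at least 2-fold. Of the 3884 genes 1170 were positive and 2714 negative. That split depended on scaling, with 757 positive and 3406 negative after centring each array on its median and 1643 and 1826 after quantile normalization.

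In LNCaP cells with control siRNA, DHT raised androgen-induced genes and lowered androgen-repressed genes. Of 24 androgen-induced genes 23 rose and none fell (23 when adjusted over the list alone), with a median of 2.48. KLK3 rose by 5.62 ± 0.13, KLK2 by 4.95 ± 0.07, FKBP5 by 3.46 ± 0.04 and the metalloreductase gene STEAP4 by 6.50 ± 0.12 (SE, n = 3 per group). The KLK3 value can be too small, as its DHT arrays lie near the array maxima. Another KLK3 probe set rose far less, from 7.48 to 7.59 with vehicle to 7.71 to 7.94 with DHT. Of 10 androgen-repressed genes 8 fell and none rose, with a median of -0.97, led by OPRK1 at -3.49 ± 0.07, CAMK2N1 at -2.55 ± 0.05 and UGT2B15 at -2.49 ± 0.04. Camera gave adjusted p-values of 3e-26 and 2.67e-05. After centring each array on its median 6 androgen-repressed genes fell and 1 rose, and after quantile normalization 6 fell and none rose. Outside the lists the largest rises included SLC38A4, an amino acid transporter, at 6.02 ± 0.10, CCDC141 at 5.98 ± 0.08, the cold-sensing channel TRPM8 at 5.79 ± 0.08 and the transcription factor SNAI2 at 4.76 ± 0.10. The largest falls were in SI, the sucrase-isomaltase, at -3.72 ± 0.09, the transporters ABCG2 and ABCA1 at -3.50 ± 0.07 and -3.43 ± 0.09, and BASP1 at -3.26 ± 0.10. KLK2, STEAP4, SLC38A4, CCDC141 and SNAI2 with vehicle and SI and ABCA1 with DHT had means below 5.88, so their sizes can be too small. Several sizes also depended on the choice of probe set. Averaging a gene's probe sets put SLC38A4 at 3.55, CCDC141 at 3.81, TRPM8 at 2.83, ABCA1 at -1.72 and BASP1 at -1.57. TRIM24 rose by 0.44 ± 0.05.

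Lipid synthesis and mitotic genes rose with DHT. Of 19 cholesterol and fatty acid synthesis genes 10 rose and 1 fell (10 and 1 when adjusted over the list alone; camera adjusted p = 0.000743), with HMGCS1 and IDI1 of the mevalonate pathway at 1.42 ± 0.06 and 0.74 ± 0.03. The most variable probe set of IDI1 was at -0.02 (adjusted p = 0.88). Of 30 G2/M and mitosis genes 21 rose and none fell (24 when adjusted over the list alone; median 0.32, camera adjusted p = 1.55e-07), with KIF20A at 0.67 ± 0.04 and TTK, a spindle checkpoint kinase, at 0.80 ± 0.09. Of 29 G1/S genes 13 rose and 3 fell (camera adjusted p = 0.00316; adjusted p = 0.0907 with an estimated correlation), with RRM2 at 1.31 ± 0.06. Of 13 luminal epithelial markers 6 rose and 3 fell (camera adjusted p = 0.0408; adjusted p = 0.0822 with an estimated correlation), with KRT19 and KRT8, both keratins, at 2.62 ± 0.12 and 0.93 ± 0.04. As the mean of its probe sets KRT19 was at 1.375. All 4 measured basal markers fell (camera adjusted p = 0.0482; adjusted p = 0.0907 with an estimated correlation), with DST, a cytoskeletal linker, at -0.76 ± 0.04. A further probe set of the basal marker ITGB4 changed the other way, at 0.21. Of 19 p53 target genes 11 fell and 2 rose (camera adjusted p = 0.0371; adjusted p = 0.074 with an estimated correlation), with SESN1 at -0.81 ± 0.03. Of 20 ER stress and amino acid response genes 12 rose and 6 fell (camera adjusted p = 0.0369; adjusted p = 0.114 with an estimated correlation), with DNAJB9, an ER chaperone partner, at 1.01 ± 0.03. After quantile normalization the luminal, basal and ER stress lists had adjusted p-values of 0.0623, 0.0787 and 0.0618. In limma 6222 genes passed, 2635 higher and 3587 lower, with 272 up and 190 down at least 2-fold. The excess of lower genes depended on scaling, with 2904 higher and 2901 lower after centring each array on its median and 2458 and 3855 after quantile normalization. The groups did not overlap for 52.5% of genes against 10% by chance.

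With TRIM24 siRNA, DHT still raised 23 of 24 androgen-induced genes, with a median of 2.60 (23 when adjusted over the list alone; camera adjusted p = 4.59e-27). MED28, a Mediator subunit named after its value was seen, fell by 0.20 ± 0.04, and its most variable probe set was at -0.09 (adjusted p = 0.259). KLK3 rose by 6.03 ± 0.13, TMPRSS2 by 2.87 ± 0.04 and FKBP5 by 3.75 ± 0.04 (SE, n = 3 per group). KLK3 ended near the array maxima with either siRNA, so its 2 rises are not a measure of a larger response here; they start from arrays of 8.01 to 8.06 with TRIM24 siRNA and 8.38 to 8.57 with control siRNA. Of 10 androgen-repressed genes 7 fell and 1 rose (median -0.85, camera adjusted p = 0.00106), with OPRK1 at -3.06 ± 0.07 and UGT2B15 at -1.75 ± 0.04. Interferon genes fell with DHT in these cells. Of 28 members 21 fell and none rose (22 when adjusted over the list alone; median -0.30, camera adjusted p = 1.31e-05), with IRF9, a transcription factor of the interferon response, at -0.59 ± 0.04, OASL at -0.59 ± 0.04 and RSAD2 at -0.73 ± 0.06. With control siRNA 7 interferon genes rose and 6 fell (camera adjusted p = 0.952), the median and mean were -0.04 and camera's direction was up. Of 18 glycolysis genes 9 rose and 2 fell with TRIM24 siRNA (11 and 2 when adjusted over the list alone; camera adjusted p = 0.000532), with HK2 at 1.32 ± 0.05. Of 19 lipid synthesis genes 14 rose and 1 fell (camera adjusted p = 2.44e-06), with FASN, the fatty acid synthase, at 0.84 ± 0.05. Of 30 mitosis genes 13 rose and none fell (camera adjusted p = 0.000532; adjusted p = 0.0816 with an estimated correlation). Of 29 G1/S genes 10 rose and 6 fell (camera adjusted p = 0.321), with a median of -0.02 and a mean of 0.08. Of 19 p53 target genes 13 fell and 2 rose (camera adjusted p = 0.00707), with TP53INP1 at -1.42 ± 0.04. Of 20 ER stress genes 11 rose and 5 fell (camera adjusted p = 0.0193; adjusted p = 0.106 with an estimated correlation), with DNAJB9 at 0.86 ± 0.03. In limma 5924 genes passed, 2301 higher and 3623 lower, with 273 up and 204 down at least 2-fold. The groups did not overlap for 56.4% of genes against 10% by chance. Both DHT comparisons shared 1783 higher and 2516 lower genes, against 445.6 and 955.1 for independent lists, and their fold changes correlated at 0.92 across genes.

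The interaction of knockdown and DHT tested where the hormone response differed between the siRNAs. It equals the knockdown change with DHT minus that with vehicle. For interferon genes 14 of 28 interactions were negative and none positive (15 and 1 when adjusted over the list alone; median -0.23, camera adjusted p = 8.55e-10), with IFIT2 at -0.71 ± 0.08, IFIT3 at -0.69 ± 0.06 and OASL at -0.66 ± 0.06. For androgen-repressed genes 6 of 10 were positive and none negative (7 and 1 when adjusted over the list alone; median 0.48, camera adjusted p = 2.49e-06), with UGT2B17 at 0.97 ± 0.10, UGT2B15 at 0.74 ± 0.05 and CAMK2N1 at 0.66 ± 0.07; 3 of the 6 are UGT2B paralogs that can share signal. Of 18 glycolysis genes 5 had positive interactions and none negative (9 when adjusted over the list alone; camera adjusted p = 1.32e-06), with SLC2A1, a glucose transporter, at 0.76 ± 0.09 and HK2 at 0.57 ± 0.07. Cell cycle genes leaned negative, with 5 of 29 G1/S genes (camera adjusted p = 0.000111; adjusted p = 0.0534 with an estimated correlation) and 8 of 30 mitosis genes (camera adjusted p = 0.000319; adjusted p = 0.0988 with an estimated correlation) and none positive. For androgen-induced genes 5 were positive and 2 negative of 24 (5 and 2 when adjusted over the list alone; camera adjusted p = 0.566), with MAF at 1.04 ± 0.14, SLC45A3 at 0.70 ± 0.08, ZBTB10 at -0.62 ± 0.09 and the elongation factor partner EAF2 at -0.60 ± 0.08. The mean of its probe sets put SLC45A3 at 0.015 (adjusted p = 0.94), and the most variable probe set put CAMK2N1 at 0.15 (adjusted p = 0.274). The median of -0.01 turned to 0.01 after quantile normalization and the mean was 0.04. Single genes with the largest interactions were CP, the copper carrier ceruloplasmin, at 1.63 ± 0.19 (-1.56 with vehicle and 0.07 with DHT), PLOD2, a collagen lysyl hydroxylase, at 1.61 ± 0.17 (-0.26 and 1.35), NPPC, the C-type natriuretic peptide, at 1.41 ± 0.09 (-0.14 and 1.27) and TCIM at -1.19 ± 0.13 (0.54 and -0.64). CP with DHT, and PLOD2, NPPC and TCIM with vehicle, had means below 5.88, so these values are uncertain in size. TRIM24 had an interaction of -0.14 ± 0.08 (adjusted p = 0.259), or -0.34 (adjusted p = 0.00197) as the mean of its probe sets. In limma 1507 genes passed, 10 of them at least 2-fold, and 993 passed without a low-value filter. Of the 1507 genes 732 were positive and 775 negative. That split turned with scaling, with 474 positive and 725 negative after centring each array on its median and 910 and 680 after quantile normalization.

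**Figure D3:**
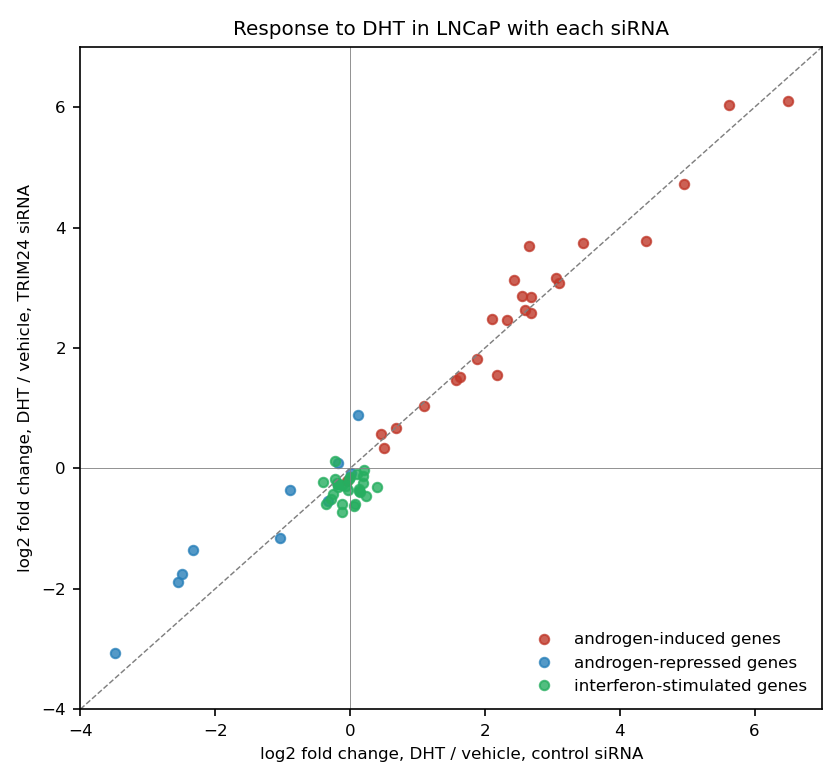
Log2 fold change with DHT over vehicle in LNCaP with control siRNA (horizontal axis) and with TRIM24 siRNA (vertical axis) for androgen-induced, androgen-repressed and interferon-stimulated genes; the dashed line marks equal response. The androgen-induced medians are 2.48 and 2.60 and the interferon medians -0.04 and -0.30.

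Genes that DHT changed in control cells were then followed through the knockdown. The 2635 genes higher with DHT had a median knockdown change of 0.019 in LNCaP with vehicle, -0.053 with DHT and -0.104 in LNCaP-abl. The share that fell was 25.7%, 36.4% and 44.8%, against 18%, 20.8% and 28.8% of all genes, and the share that rose was 28.6%, 20.6% and 14.2%, against 20.5%, 19.4% and 16.7%. The vehicle median turned negative, to -0.003, without the third control vehicle array and to -0.088 for the 272 genes that DHT raised at least 2-fold. For those 272 genes it was -0.108 with DHT and -0.159 in LNCaP-abl. The LNCaP-abl median of DHT-higher genes was -0.138 after centring each array on its median and -0.057 after quantile normalization. The 3587 genes lower with DHT had medians of -0.014, 0.048 and -0.001. Without the second control DHT array the DHT-higher median with DHT was -0.078. Without the first or second control vehicle array the DHT-lower median with vehicle was -0.025 or -0.03, and without the second control DHT array that of LNCaP-abl was 0.01. The DHT comparison shares control arrays with both LNCaP knockdown comparisons. Simulated unchanged groups on those arrays gave medians of 0.004, -0.005 and 0 for the DHT-higher genes and -0.005, 0.005 and 0 for the DHT-lower genes. Genes were drawn independently there, so no shift shared by the genes of an array entered, and the simulated medians may vary too little. The fold change covariance across genes was -0.000476, -0.0146 and -0.0181 against 0.00239, -0.00247 and 5.5e-05 simulated. In the LNCaP comparisons part of any excess may come from the shared controls, since 3 arrays are too few to divide. The LNCaP-abl knockdown shares no arrays with the DHT comparison. For the DHT-higher genes as a set, camera gave a p of 0.879, 0.00212 and 7.81e-06, and with an estimated correlation a p of 0.952, 0.238 and 0.0961.

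Without knockdown, LNCaP-abl differed from LNCaP in cell cycle and interferon genes. All 30 G2/M and mitosis genes were higher in LNCaP-abl (30 when adjusted over the list alone), with a median of 1.77, and 28 of 29 G1/S genes were higher, with a median of 0.98. HMMR, a spindle-associated protein, was higher by 2.65 ± 0.07, NUSAP1 by 2.30 ± 0.05 and RRM2 by 2.83 ± 0.06 (SE, n = 3 per group). The G1/S member that was lower, named after its value was seen, was the cyclin gene CCNE1 at -0.48 ± 0.05. Of 28 interferon-stimulated genes 26 were lower and 1 higher, with a median of -1.43. IFITM1 was at -2.92 ± 0.05, IFI6 at -2.69 ± 0.05 and ISG15, a ubiquitin-like modifier, at -1.99 ± 0.04, while IFIT5 was higher by 0.72 ± 0.07. Camera gave adjusted p-values of 7.49e-16, 9.24e-12 and 5.36e-11. Androgen-induced genes were mixed, with 6 higher and 11 lower of 24 (camera adjusted p = 0.295), MAF at -5.27 ± 0.10, KLK3 at -2.80 ± 0.13 and CENPN at 1.41 ± 0.04. Single genes reached larger sizes than with knockdown or DHT. TMEFF2 was at -9.15 ± 0.06, the transcription factor ETV1 at -7.96 ± 0.11 and the semaphorin SEMA3C at -7.52 ± 0.06, while CD200 was at 7.66 ± 0.06, FLRT3 at 7.29 ± 0.10 and NR3C1, the glucocorticoid receptor, at 6.79 ± 0.09. MAF, KLK3, TMEFF2, ETV1 and SEMA3C in LNCaP-abl and CD200, FLRT3 and NR3C1 in LNCaP had means below 5.88, so these differences can be too small. Some also depended on the choice of probe set. Averaging a gene's probe sets put TMEFF2 at -4.16, ETV1 at -2.80, MAF at -1.62, CENPN at 0.70 and CCNE1 at -0.19. A further KLK3 probe set read 8.86 to 8.89 in LNCaP and 5.01 or less in LNCaP-abl. Another differed far less, at 7.48 to 7.59 in LNCaP and 7.05 to 7.31 in LNCaP-abl. TRIM24 differed by -0.17 ± 0.05 (adjusted p = 0.012), by -0.13 (adjusted p = 0.0684) without the first LNCaP-abl array and by -0.04 (adjusted p = 0.45) as the mean of its probe sets. In limma 8675 of 13607 genes passed, 3962 higher and 4713 lower, with 668 and 680 at least 2-fold. The groups did not overlap for 66.6% of genes against 10% by chance. Culture history and cell line differ together in this comparison.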

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

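Tests chosen after the result was seen are the splits with the shared knockdown effect removed, the question of the siRNA sequence and the comparison of knocked-down LNCaP-abl with control LNCaP; the other tests were written down before their result.

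The effect of knockdown differed between LNCaP-abl and LNCaP by a test of the difference itself for 3884 genes. The lists that differed were G2/M and mitosis (median -1.13), G1/S and DNA replication (-0.87), MYC-linked (-0.21), glycolysis (-0.08; adjusted p = 0.197 with an estimated correlation), androgen-repressed (0.39), p53 target (0.08) and ER stress genes (0.05; adjusted p = 0.096 with an estimated correlation). The genes with the largest differences were MCM10 at -2.19, ZNF367 at -2.13, SHCBP1 at -2.09, DEPDC1B at -2.03, DTL at -2.01, NAALADL2 at 1.52, PSLNR at 1.33, MAF at 1.30, CP at 1.01 and the pseudogene CYP4F30P at 0.95. Apart from PSLNR each of these has a group mean below 5.88 in the comparison, so the sizes are uncertain.

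The effect of knockdown differed between DHT and vehicle in LNCaP by a test of the difference itself for 1507 genes. The lists that differed were androgen-repressed (0.48), interferon-stimulated (-0.23), G2/M and mitosis (-0.17; adjusted p = 0.0988 with an estimated correlation), G1/S and DNA replication (-0.14; adjusted p = 0.0534 with an estimated correlation) and glycolysis genes (0.13). The genes with the largest differences were CP at 1.63, PLOD2 at 1.61, NPPC at 1.41, TMPRSS11E at 1.23, STYXL2 at 1.15, TCIM at -1.19, SMIM31 at -1.07, FRY at -1.02, CAMK2D at -0.95 and SGTB at -0.93. CP, PLOD2, NPPC, TMPRSS11E, STYXL2 and TCIM each have a group mean below 5.88 in the comparison, so their sizes are uncertain.

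The larger fall of cell cycle genes in LNCaP-abl could come from a signal floor in LNCaP, where these genes are dimmer, but the 19 members bright in LNCaP, at or above 7.71, kept a median interaction of -0.81 and 100% of them lay below 0, against -1.05 for all 59. Degraded RNA could also lower it. The interaction of the list mean was -1.02 without the 3' to 5' covariate and -1.02 with it (95% interval -1.09 to -0.95). With knockdown the GAPDH signal moved from 0.52 to 0.59 in LNCaP with vehicle and from 0.56 to 0.64 in LNCaP-abl. That of ACTB moved from 1.87 to 2.05 and from 1.88 to 1.99. With such similar shifts in both lines the covariate could hardly change the interaction, so its test cannot decide. A narrower distribution of values on the LNCaP-abl knockdown arrays could do so too, but after quantile normalization the median interaction was -1. Neither the signal floor nor the narrower distribution accounts for the whole difference. LNCaP-abl and LNCaP differ in much besides their need for androgen, so a difference in dependence on TRIM24 stays open beside others.

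The interferon-stimulated list rose less with knockdown under DHT than under vehicle, by -0.28 in the list mean. RNA quality could differ between the conditions. With the 3' to 5' covariate the value was -0.29 (95% interval -0.34 to -0.23). The covariate's effect was estimated only from the small scatter within groups, so this value cannot decide and RNA quality stays open. A response to the siRNA duplex itself, which might differ with hormone, cannot be told apart from loss of TRIM24, because nothing here separates siRNA sequence from target. The value of -0.28 does not decide between them.

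Of 13607 genes 38.5%, 40.2% and 45.6% were called in the knockdown comparisons, at a median size of 0.26. Separate array batches for each group could give this, but the changes of 12313 genes under 0.5 in size correlated at 0.52 across genes between LNCaP with DHT and LNCaP-abl, which share no arrays; batches that follow the siRNA in both stay open. RNA quality could give it as well. Across called genes the covariate-adjusted changes followed the unadjusted ones with a slope of 0.99 or more. The covariate's effect was estimated only from scatter within groups, with an SD of 0.01 to 0.03 for GAPDH and 0.05 to 0.09 for ACTB. Scatter this small may be measurement error, so the slope cannot decide and RNA quality stays open. The median SE rose from 0.05 to 0.07, 0.09 and 0.06 in LNCaP with vehicle, LNCaP with DHT and LNCaP-abl, and the calls went from 5236, 5468 and 6201 to 3773, 2669 and 4964. Calls ended as the errors widened, so the count with DHT is not kept.

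The arrays of each 2-group comparison were also split in the 10 possible ways. With 3 arrays against 3 the splits are too few for a share under 0.05. In LNCaP with vehicle, LNCaP with DHT and LNCaP-abl only 1 split, the real one, gave as many calls as the 5236, 5468 and 6201 found, and the highest other split gave 1, 0 and 10. For DHT with control and TRIM24 siRNA and for LNCaP-abl against LNCaP it was also 1 split, and the highest other gave 0, 1 and 0. For each interaction 100 splits were examined, the real one and a random draw of the other possible ones. For the interaction with DHT, 11 of 100 splits, the real one included, gave at least 1507 calls and the highest gave 6546. This share is not under 0.05, so by the rule set beforehand the splits do not argue against an accidental division of the arrays. The split with 6546 calls kept each group whole and added the knockdown effects with vehicle and with DHT, so it was no accidental division. All 10 splits with as many calls besides the real one, this one included, placed the TRIM24 siRNA arrays unequally between the sides. The shared knockdown effect thus entered the interaction, so the rule cannot decide here. The 44 splits with equal placement gave at most 0. With the shared effect removed 1 split of 100, the real one, gave as many, and the highest other gave 2. For the interaction with cell line 1 split of 100, the real one, gave 3884 calls and the highest other gave 3228. The split that adds the knockdown effects of both lines was not in this draw, so this count is not comparable with that for DHT. The 43 splits with equal placement gave at most 1. With the shared effect removed only the real split gave as many, with 449 as the highest other. In both interactions the removed effect was estimated from the real grouping, which keeps the real count by construction. Splits with equal placement mix knockdown and control arrays on each side, which widens the errors. These added results therefore cannot replace the first counts of splits. Neither decides whether an accidental division of the arrays gave the interactions.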

How the results depend on the processing

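Of 553 alternatives to 26 results 492 left the result unchanged: a list its direction and side of the threshold, a count within 1.5 times and a median of DHT-called genes within the spread between arrays. Of the others 42 moved counts or medians further, 11 list calls were lost, 6 gained, and 2 reversed the median of DHT-higher genes with vehicle. Leaving the cell cycle lists out of the DHT sets, 6 of the 492, takes out too few genes to show stability. For 234 values of named genes 4129 of 4167 kept direction and side, with 35 weaker and 1 stronger. IDI1 with control siRNA and DHT turned to -0.023 with the most variable probe set, and TRIM24 in the interaction with line, not called, to 0.016 with quantile normalization. The mitosis list kept its call under each alternative in the 3 knockdown comparisons, as did the G1/S list in LNCaP-abl. Averaging the probe sets of a gene moved 73 of 224 values of named genes by over 1.5 times, 72 of them to smaller sizes. Signal over background limits dim genes, whose changes are compressed. The covariate, and the DHT sets without cell cycle genes, were chosen after seeing the data. Where no construction shows it, the cause was not tested.

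Testing every probe set on its own raised the counts to 8888, 9316, 10561, 10447, 9945, 15349 and 5933 (knockdown with vehicle, with DHT and in LNCaP-abl, DHT with control and TRIM24 siRNA, the lines, and the interaction with line), because it tests more features. A 2-fold threshold left 106, 106, 171, 462, 477, 1348, 10 and 109, and an adjusted p of 0.01 left 652 and 2216 for the interactions with DHT and line. Without a filter the interaction with DHT had 993 calls. With the 3' to 5' covariate knockdown with DHT had 2669, and shared calls were 1964 within LNCaP and 1956 between LNCaP with DHT and LNCaP-abl. The higher and lower split moved by over 10 points for knockdown in LNCaP-abl, from 2276 and 3925 to 1608 and 4528 with centring and 3022 and 3126 with quantile normalization, and for the interaction with line, from 1170 and 2714 to 757 and 3406 and to 1643 and 1826.

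Androgen-induced genes lost their call with the most variable probe set with vehicle (-0.065, adjusted p = 0.0971), and with DHT with the stricter filter (-0.15, 0.0711), the most variable probe set (-0.111, 0.0963), an estimated correlation (-0.113, 0.0853) and the covariate (-0.094, 0.0806). In LNCaP-abl they passed without a filter (-0.205, 0.00445), with quantile normalization (-0.141, 0.0172) and with fry (-0.205, 9.27e-10), which asks another question, whether the list differs from no change rather than from other genes. G1/S genes with DHT lost theirs with the stricter filter (-0.091, 0.228), the most variable probe set (-0.126, 0.0507), an estimated correlation (-0.139, 0.246) and the covariate (-0.109, 0.222).

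Medians of DHT-higher genes were -0.088 (reversed), -0.108 and -0.159 for 2-fold DHT calls, and in LNCaP-abl -0.082 with mean probe sets, -0.127 with the most variable one, -0.138 with centring and -0.057 with quantile normalization. For DHT-lower genes with vehicle they were -0.029 without a filter, -0.001 with the stricter filter, -0.007 with centring and -0.002 for 2-fold calls; with DHT 0.03 with the covariate; in LNCaP-abl -0.017 (stricter filter), 0.013 (mean), -0.039 (centring), 0.03 (quantile), -0.026 (2-fold) and -0.011 (covariate).

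Without 1 array the counts were 4572 to 4828, 4853 to 5123, 5472 to 6007, 5535 to 6004, 5320 to 5519, 8170 to 8349, 1036 to 1600 and 3170 to 3901. List medians were -0.156 to -0.113, -0.154 to -0.054 and -0.219 to -0.184 (androgen-induced), -0.461 to -0.417, -0.628 to -0.567 and -1.726 to -1.681 (mitosis) and 0.011 to 0.049, -0.145 to -0.11 and -0.891 to -0.842 (G1/S). Shared calls were 3126 to 3376, 2631 to 2844 and 3144 to 3355. DHT-higher medians were -0.003 (reversed) to 0.032, -0.078 to -0.05 and -0.111 to -0.098, and DHT-lower medians -0.03 to -0.008, 0.04 to 0.063 and -0.01 to 0.01.

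With a replicate block the counts were 5082, 5328, 6050, 6136, 5833, 7658, 1246 and 3617. Arrays of a number correlated at -0.3 to 0.2 and most did not correlate best with their own number. The block changed no call of the androgen-induced, mitosis or G1/S lists.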

Other observations

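Other genes and lists were measured in the knockdowns as well. SPOP, a ubiquitin ligase adaptor often mutated in prostate cancer, fell by 0.34 ± 0.04 in LNCaP with vehicle, 0.41 ± 0.04 with DHT and 0.43 ± 0.04 in LNCaP-abl, and KAT2B, an acetyltransferase, by 0.32 ± 0.06, 0.37 ± 0.06 and 0.37 ± 0.06 (SE, n = 3 per group). NCOA2, a transcriptional coactivator, fell by 0.46 ± 0.04, 0.56 ± 0.04 and 0.34 ± 0.04, and a further probe set of it was at 0.26 in LNCaP-abl. Lipid synthesis genes moved both ways, with 8, 7 and 7 of 19 up and 5, 5 and 5 down (camera adjusted p = 0.93, 0.511 and 0.287). SQLE, the squalene epoxidase, fell by 0.93 ± 0.04, 0.74 ± 0.04 and 0.76 ± 0.04, while SREBF1, a lipid transcription factor, rose by 0.33 ± 0.04, 0.63 ± 0.04 and 0.58 ± 0.04. ER stress genes were mixed too, with 6, 5 and 9 of 20 up and 5, 5 and 5 down (camera adjusted p = 0.982, 0.914 and 0.112). SLC7A11, the cystine transporter, was at -1.27, -1.47 and -1 (each ± 0.07), and MANF, an ER-resident factor, rose by 0.48 ± 0.03, 0.49 ± 0.03 and 0.39 ± 0.03. In LNCaP this list's medians of 0.05 and 0.01 stood against means of -0.08 and -0.08.

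Retinoic acid-induced genes, of interest because TRIM24 binds retinoid receptors, did not move together. Of 8 measured members 1, 3 and 2 rose and 1, 1 and 1 fell (camera adjusted p = 0.982, 0.803 and 0.188), with PLAAT4 at 0.82 ± 0.06, 0.20 ± 0.06 and 0.72 ± 0.06 and DHRS3, a retinaldehyde reductase, at -0.62 ± 0.05, -0.38 ± 0.05 and -0.30 ± 0.05. Of 13 luminal markers 4, 3 and 4 rose and 3, 4 and 5 fell (camera adjusted p = 0.93, 0.914 and 0.879). ESRP1, an epithelial splicing regulator, rose by 1.02 ± 0.05, 0.87 ± 0.05 and 0.44 ± 0.05, and SPDEF, an epithelial transcription factor, fell by 0.51 ± 0.04, 0.36 ± 0.04 and 0.26 ± 0.04. As the mean of its probe sets SPDEF in LNCaP-abl was at -0.08 (adjusted p = 0.121), and without the third knockdown array PLAAT4 with DHT was at 0.16 (adjusted p = 0.0645). Of 4 basal markers 1, 2 and 2 rose (camera adjusted p = 0.823, 0.272 and 0.0609), with DST at 0.84 ± 0.04, 0.57 ± 0.04 and 0.60 ± 0.04. In LNCaP with vehicle the basal median of -0.05 and mean of 0.16 had different signs. Fibroblast and mesenchymal markers (0, 2 and 1 up and 2, 1 and 3 down of 10; camera adjusted p = 0.91, 0.914 and 0.879), neuroendocrine markers (0, 0 and 1 up and 0, 0 and 1 down of 4; camera adjusted p = 0.93, 0.803 and 0.823) and leukocyte and endothelial markers (none of 3; camera adjusted p = 0.93, 0.804 and 0.316) passed in no knockdown comparison. FN1, the matrix protein fibronectin, fell by 0.35 ± 0.05, 0.46 ± 0.05 and 0.25 ± 0.05. MYC rose in each knockdown, by 0.44 ± 0.04, 0.62 ± 0.04 and 0.23 ± 0.04, while the MYC-linked list passed in LNCaP-abl alone.

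The test of a return to the LNCaP level was chosen after the result was seen. The hypothesis was that knockdown brings the cell cycle genes of LNCaP-abl to the level of control LNCaP with vehicle. The G2/M and mitosis median differed by 0.01 after knockdown, against 1.77 before it, with 7 members higher and 8 lower of 30 (camera adjusted p = 0.585), and the G1/S median by 0.04 against 0.98, with 12 higher and 8 lower of 29 (camera adjusted p = 0.369). The lists may have returned as a whole, but members lay on both sides, so the question stays open. The interferon list did not reach the LNCaP level, with a median of -0.94 against -1.43 before and 23 of 28 members lower (camera adjusted p = 1.23e-05).

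The hypothesis that cell cycle genes account for the fall of DHT-raised genes in LNCaP-abl was tested by leaving their lists out. The median was -0.10 without the 34 members among the 2635 DHT-higher genes and -0.104 with them. This test is void, because leaving out the 34 lowest genes instead also gave -0.10, and cell cycle genes outside the 2 lists stayed in. The question stays open.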
